A study of Mus musculus with 8 samples.

How the data were processed

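Libraries were made with an Illumina TruSeq RNA kit from total RNA extracted with Trizol, per the labels' protocols. The labels list 8 libraries of marginal zone B cells, 4 per group. Per the submitters' processing notes, the authors used cutadapt 1.8.1, TopHat2 2.0.14 and Cuffdiff 2.2.1 with the mm10 build; the gene annotation, the alignment settings and the filters are not given in the sources used here. Per the file headers, the deposited table is Cuffdiff's table of fragment counts per condition. It names 23997 genes by symbol and gives, for each of 2 conditions (q1 and q2), an estimated count, its variance, and the parts of the variance due to isoform assignment and to dispersion. No gene had an isoform assignment part above 0 in either column, so the SDs given below include no such error. The estimated counts the authors deposited are not whole numbers (2.12% of those above 0 in q1 lay within 0.01 of one), and the median ratio of the columns is near 1, as after scaling to a common size, but the scaling is not stated in the file. Only these values pooled over the libraries of a condition were used, so the spread between mice cannot be seen.

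The columns were not assigned to ACKR3+ or ACKR3- cells, because q1 and q2 match no label, and neither the order of the samples nor the level of any gene was used to assign them. A quasi-likelihood test on 8 libraries had been planned for a table of counts per library. The alternative written down before the data were examined, for a table of 1 value per condition, was used in its place: no test, no p-value, and a description by size. The log2 ratio of q2 over q1 was computed with a pseudocount of 1, which understates the change of low genes, for the 9582 genes with at least 100 fragments in the higher column. A difference of at least 2-fold was the size rule. The SD of each log2 ratio was taken to first order from the deposited variances.

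What these variances measure limits the errors given. The coefficient of variation they imply was within 10% of the running median over 101 genes of similar count for 89.1% of genes in each column, so the variance follows mainly the count and not the gene. The running median fell from about 18.2% at 100 fragments to a lowest value of 8.6%. It was higher again for abundant genes, with 11.0% at the count of Cr2 in q1. Whether the variance refers to 1 library or to the mean of a condition is not stated. The median absolute log2 ratio was 0.45 of its SD, where unchanged genes with normal errors of that SD would give 0.67. Exact (Clopper-Pearson) 95% intervals are given for the ratios of genes with fewer than 3 fragments in one column; they cover counting error only and treat estimated fragments as counts. The total fragments of a column, 16877559 in q1 and 16653774 in q2, limit values near 0 more than those of abundant genes.

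Gene lists (30, fixed before the data were examined) covered B cell states, signalling pathways and markers of other cells: marginal zone, follicular, transitional and immature, B-1, germinal center, plasma cell, and memory and age-associated B cells; the Notch pathway, chemoattractant receptors, CXCL12 and ACKR3 partners, integrins and adhesion, B cell receptor signalling, immediate early genes, heat shock, Toll-like receptor signalling, NF-kB and TNF family, type I interferon response, antigen presentation, cell cycle, unfolded protein response, cholesterol synthesis and glycolysis; and markers of T cells, NK cells, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells, platelets, and stromal and endothelial cells. For the 24 lists with at least 5 members of 100 fragments, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these 2 columns and is not a p-value. The genes named in the text were chosen by a rule set in advance: Ackr3; Cr2, Cd1d1, Cd9, S1pr1, S1pr3, Fcer2a, Cxcr4, Cxcr5 and Notch2; the 10 largest ratios each way; and up to 4 members per list with the largest absolute ratio. The rule gave 113 genes, of which not all are reported here; others, including Cd3e and Cd4, are values chosen after they were seen.

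Gene positions were taken from GENCODE M21 (GRCm38, the assembly named mm10 in the notes), to which 22694 symbols matched directly and 929 through a RefSeq synonym. Transcript length and GC content were those of the longest M21 transcript. Alternatives were minimums of 20 and 500 fragments, pseudocounts of 0 and 10, and scaling to equal totals or by the median ratio; added after seeing the data were a 1.5-fold rule, a further requirement of 2 deposited SD, the removal of Y-linked genes and Xist, and a correction for GC content, length and mean expression. Random lists were redrawn under each alternative that changed the ratios or the genes. The calculations were tested on simulated data drawn with the deposited variances, with 200 genes changed: 46 of 50 genes with a 4-fold change and 22 of 50 with a 2-fold change were returned at 2-fold or more in the right direction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.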

Results

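RNA sequencing was performed on marginal zone B cells (MZBs) of C57BL/6 mice, the splenic B cells that line the marginal sinus and respond early to blood-borne antigen. The labels describe 8 libraries, 4 of ACKR3+ and 4 of ACKR3- MZBs, given as genotypes, and the titles name the groups by GFP. ACKR3 is an atypical chemokine receptor that binds and removes CXCL12. The comparison set up by the design asks which transcripts differ between MZBs with and without this receptor. The processed table does not give a value per library. It holds 1 estimated fragment count per gene for each of 2 conditions, called q1 and q2, together with a variance for each estimate. No label or column header ties q1 or q2 to the ACKR3+ or the ACKR3- cells, so every value below is given by column name and no direction with respect to ACKR3 is assigned. The counts summed to 16877559 fragments in q1 and 16653774 in q2, and the depth of each single library is unknown. Because each condition has 1 value, no difference has a replicate check and no p-value is given. Log2 ratios are q2 over q1, and the value after ± is the SD of that ratio implied by the deposited variances. Ratios are given for the 9582 genes with at least 100 fragments in the higher column, whose median log2 ratio was 0.00.

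The receptor itself differed strongly between the columns. Ackr3 (chromosome 1, 90203980 to 90216751, GRCm38) had 1030 fragments in q1 and 149 in q2, a log2 ratio of -2.78 ± 0.27 and a 6.87-fold difference. Among the 24 chemoattractant receptors on the list, 16 reached 100 fragments. Ackr2, the related scavenger of inflammatory CC chemokines, was also higher in q1, with 3139 against 1814 fragments and a log2 ratio of -0.79 ± 0.18. Higher in q2 were S1pr2, the receptor that retains B cells in germinal centers, at 3.81 ± 0.49, and Cxcr3, the receptor for interferon-induced chemokines, at 1.75 ± 0.35. Cxcr4, the signalling receptor for CXCL12, had 1049 fragments in q1 and 1500 in q2, at 0.52 ± 0.19. Cxcr5, the receptor that guides B cells to follicles, was near equal at -0.03 ± 0.18. The receptor list had a median of -0.10 and a mean of 0.13, with 9 members higher in q1 and 7 in q2, and its median lay at percentile 2.95 of random lists. In the list of CXCL12 and ACKR3 partners the median was -0.02, at percentile 43.3; Ackr3 is itself a member. In that list Grk5, a receptor kinase, stood at -0.30 ± 0.23 and Calcrl, the calcitonin receptor-like receptor, at 0.39 ± 0.28.

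Across the transcriptome the columns were close. Of the 9582 genes, 2.28% were at least 2-fold apart: 176 were at least 2-fold higher in q2 and 42 in q1. With a minimum of 20 fragments these counts were 346 and 102, and with 500 they were 39 and 14. The 10 largest ratios toward q2 included genes of germinal center B cells, among them Rgs13, Gcsam, Nuggc, Mybl1, Basp1 and S1pr2, together with Chst1, Rassf6 and Slpi. Slpi, a secreted protease inhibitor, had 51.0 and 803 fragments, a log2 ratio of 3.95 ± 0.38. Rgs13 had 0.99 and 112 fragments, a ratio of 113 with an exact 95% counting interval of 19.7 to 4463. Gcsam had 2.87 and 185 fragments, a ratio of 64.2 with a counting interval of 20.8 to 302. The 10 largest ratios toward q1 were those of Atf3, Ackr3, Stc1, Adamdec1, Myo18b, Grip2, Tmod2, Adam28, Serpine2 and Sel1l3. Atf3, a stress-inducible transcription factor, had 403 fragments in q1 and 54.2 in q2, at -2.87 ± 0.40. Stc1, which encodes the secreted glycoprotein stanniocalcin, stood at -2.38 ± 0.46. Adam28 and Adamdec1, members of the disintegrin and metalloproteinase family, stood at -1.77 ± 0.25 and -2.38 ± 0.52, and Serpine2, a protease inhibitor, at -1.67 ± 0.25. When unchanged genes were simulated with the deposited variances, 103 of 9394 came out at least 2-fold apart, and 38 of them also by more than 2 deposited SD. In the data, 170 genes toward q2 and 39 toward q1 met both conditions.

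**Figure D1:**
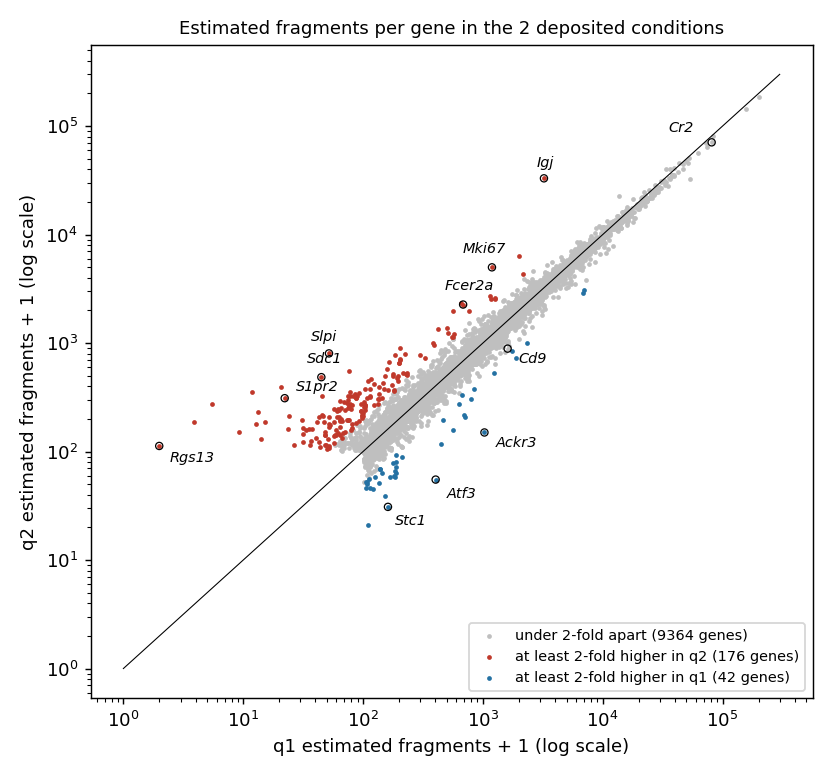
Estimated fragments per gene plus 1 in q1 (horizontal, log scale) against q2 (vertical, log scale) for the 9582 genes with at least 100 fragments in the higher column; the line marks equal values. The 176 genes at least 2-fold higher in q2 are red, the 42 at least 2-fold higher in q1 are blue, and Ackr3 (1030 and 149 fragments) lies among the latter.

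Most genes that mark MZBs were higher in q1 and most that mark follicular B cells were higher in q2. Of the 22 marginal zone genes, all above 100 fragments, 19 were higher in q1 and 3 in q2, none reached 2-fold, and the median log2 ratio of -0.32 was below that of each of 10000 random lists matched on expression. Cd9, a tetraspanin, had 1608 fragments in q1 and 888 in q2, at -0.86 ± 0.19. Asb2 stood at -0.82 ± 0.18, Cd1d1, the lipid-presenting molecule abundant on MZBs, at -0.77 ± 0.18, Nebl at -0.76 ± 0.22 and S1pr3, a sphingosine-1-phosphate receptor, at -0.62 ± 0.18. S1pr1, which holds MZBs in the marginal zone, stood at -0.30 ± 0.19. Cr2, encoding complement receptor CD21, was abundant in both columns with 81167 and 70851 fragments, at -0.20 ± 0.30, or -0.34 when corrected for GC content, transcript length and mean expression. Notch2, the receptor required for MZB development, stood at -0.05 ± 0.19, or 0.038 when corrected in the same way. Of the 15 follicular genes in the table, 10 were higher in q2, 2 of these by at least 2-fold, and 5 in q1, with a median of 0.37 above that of every random list. Fcer2a, encoding CD23, had 683 fragments in q1 and 2265 in q2, at 1.73 ± 0.20. Bach2, a repressor of plasma cell differentiation, stood at 1.37 ± 0.20, Itgb7, an integrin chain for gut homing, at 0.99 ± 0.20 and Cd200 at 0.83 ± 0.28. Of the members higher in q1, Klf2, a transcription factor of lymphocyte trafficking, had the largest ratio, at -0.26 ± 0.19. Beside these lists, the medians of germinal center (3.81), plasma cell (1.02) and T cell genes (0.41) were also toward q2 and that of macrophage genes (-1.001) toward q1.

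The Notch pathway list had 12 of 14 members higher in q1, none by 2-fold, and a median of -0.14 at percentile 0.06. Its largest ratios were those of the Notch targets Hes5, at -0.55 ± 0.27, and Dtx1, at -0.35 ± 0.19, of Notch1 itself, at -0.29 ± 0.19, and of the coactivator Maml2, at -0.27 ± 0.18. The median was -0.090 when ratios were corrected for GC content, transcript length and mean expression, at percentile 2.30 of random lists corrected alike, with Dtx1 at -0.23 and Notch1 at -0.18. Most macrophage genes (7 of 9) were higher in q1 beside this list too. Dtx1 and Notch2 are also on the marginal zone list, so the 2 lists are not separate.

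Germinal center, plasma cell and cell cycle genes were higher in q2. All 11 germinal center genes above 100 fragments were higher in q2, 8 of them by at least 2-fold, with a median log2 ratio of 3.81. In the plasmablast and plasma cell list 14 of 15 genes were higher in q2, 8 by at least 2-fold, with a median of 1.02. Irf4 was the member higher in q1, at -0.28 ± 0.18, and Prdm1 stood at 0.25 ± 0.24. Igj, the immunoglobulin joining chain, had 3234 fragments in q1 and 33006 in q2, at 3.35 ± 0.27. Sdc1, the plasma cell surface marker CD138, had 43.9 and 484 fragments, at 3.43 ± 0.40, Cd28 stood at 2.40 ± 0.46 and Txndc5, an endoplasmic reticulum disulfide isomerase, at 1.68 ± 0.19. All 27 cell cycle genes were higher in q2, 16 by at least 2-fold, with a median of 1.75, or 0.88 among members with at least 500 fragments. Among them Mki67, the proliferation antigen, had 1190 and 4991 fragments, at 2.07 ± 0.19, Ube2c stood at 2.19 ± 0.40, Cdk1 at 2.13 ± 0.38 and the mitotic kinesin Kif11 at 2.07 ± 0.26. Each of these 3 medians was above that of every random list. The unfolded protein response list had a median of 0.28, with 14 of 18 members higher in q2, again above every random list. It was led by Creld2, at 1.45 ± 0.21, Xbp1, the transcription factor of this response, at 1.02 ± 0.18, Manf, at 0.87 ± 0.19, and Sdf2l1, at 0.84 ± 0.23. Creld2 and Xbp1 are also on the plasma cell list, so the 2 lists are not separate. Markers of other cells stood beside these lists: the T cell list was also higher in q2, with a median of 0.41 over 5 genes including Cd28, whereas macrophage genes were higher in q1.

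**Figure D2:**
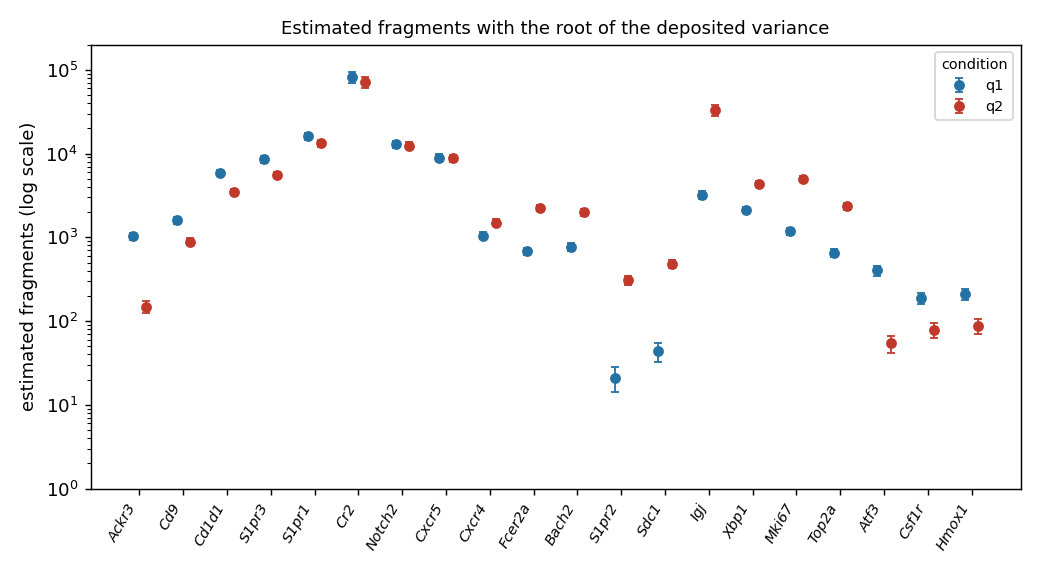
Estimated fragments (vertical, log scale) of 20 genes in q1 (blue) and q2 (red); bars show the square root of the deposited variance. Ackr3, Cd9, Cd1d1 and Atf3 lie higher in q1, whereas Fcer2a, Sdc1, Igj and Mki67 lie higher in q2.

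Lists for other B cell states gave smaller medians. Transitional and immature B cell genes had a median of 0.27 at percentile 99.2, resting on 6 genes (0.46 over 7 with a minimum of 20 fragments), with Cd93, a marker of immature B cells, at 2.19 ± 0.42 and Vpreb3 at 1.04 ± 0.27. Memory and age-associated B cell genes, 8 of them higher in q2 and 4 in q1, had a median of 0.24 at percentile 99.97, or 0.0060 at percentile 59.99 with a minimum of 500 fragments, with Tbx21, encoding the transcription factor T-bet, at 1.71 ± 0.40, Zbtb32 at 1.36 ± 0.42, Itgax at 1.13 ± 0.36 and Nt5e at 0.79 ± 0.34; Fcrl5, also on the marginal zone list, stood at -0.52 ± 0.18. The B-1 list had a median of -0.17 and a mean of 0.45, and the median became 0.19 with a minimum of 20 fragments, so that its direction depended on the summary and the minimum. Its largest ratios were toward q2, with Anxa2 at 2.86 ± 0.40 and Spn, encoding CD43, at 1.76 ± 0.30. Integrin and adhesion genes had a median of 0.09 at percentile 99.2, or 0.040 at percentile 89.9 with a minimum of 500 fragments, with Vcam1, which is also on the macrophage list, at -1.40 ± 0.38 and Itga6 at 1.03 ± 0.34. Cholesterol synthesis genes had a median of 0.22, above nearly all random lists, with 16 of 18 members higher in q2, among them Sqle at 0.73 ± 0.28 and Idi1 at 0.66 ± 0.23.

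Immediate early and type I interferon response genes were mostly higher in q1. Of 22 immediate early genes, 17 were higher in q1 and 2 of these by at least 2-fold, with a median of -0.27 below every random list. Besides Atf3, the largest ratios were those of the nuclear receptor Nr4a2, at -1.50 ± 0.41, Myc, at -0.67 ± 0.19, and Klf4, at -0.66 ± 0.20. Type I interferon response genes had a median of -0.20, also below every random list (-0.099, inside the central 95% of random lists, with a minimum of 500 fragments), with 20 of 22 higher in q1 and none by 2-fold, among them Ifit3 at -0.63 ± 0.24, Rsad2 at -0.55 ± 0.32 and Oas2 at -0.52 ± 0.19. Beside both lists, 7 of 9 macrophage markers were higher in q1, 5 of them by at least 2-fold. Toll-like receptor signalling had a median of -0.09 at percentile 0.49, and Tlr3, the sensor of double-stranded RNA, stood at -0.87 ± 0.19. Antigen presentation had a median of -0.12 at percentile 0.43, and NF-kB and TNF family genes had a median of -0.07 at percentile 1.15; corrected for GC content, length and expression these medians were -0.081 at percentile 1.45 and -0.019 at percentile 16.4, the latter inside the central 95%. B cell receptor signalling, with a median of -0.02 over 25 genes, glycolysis, with -0.01 over 16, and heat shock, with 0.07 over 10, lay inside the central 95% of random lists. In total 19 of 24 lists lay outside that range, though lists share genes and their members are not independent. Of these 19, 14 lay outside it on the same side under each alternative that gave a median; adhesion, memory, interferon and NF-kB genes came inside it under at least 1 alternative, and the B-1 list changed side.

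**Figure D3:**
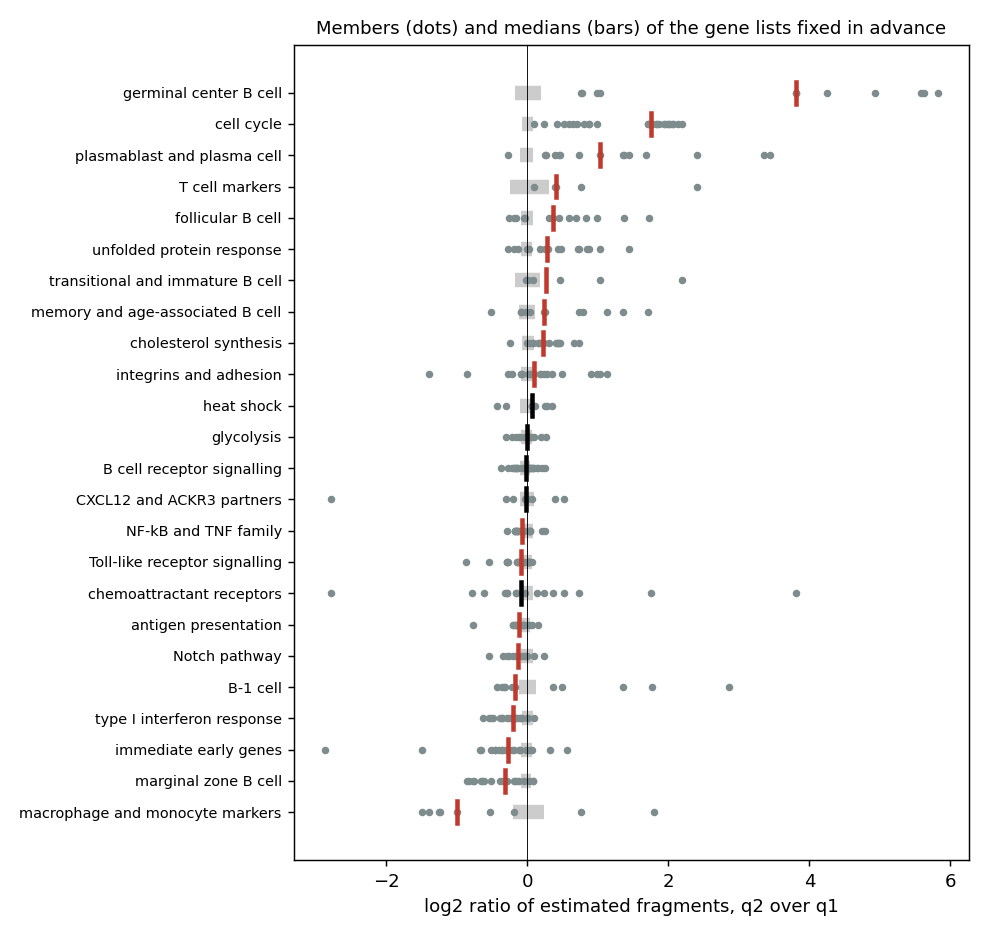
Log2 ratio of estimated fragments, q2 over q1 (horizontal), for the members (dots) of the 24 gene lists with at least 5 genes above 100 fragments; vertical bars are list medians, red where outside the grey range that holds 95% of 10000 random lists. Germinal center (3.81), cell cycle (1.75) and plasma cell (1.02) medians lie to the right and the macrophage median (-1.001) lies farthest to the left.

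Most markers of cells other than B cells lay below 100 fragments, and they did not all differ in 1 direction. Summed fragments in q1 and q2 were 6871 and 4718 for the macrophage and monocyte list and 2907 and 3590 for the T cell list. Of 9 macrophage and monocyte genes above 100 fragments, 7 were higher in q1 and 5 of these by at least 2-fold, with a median of -1.001 below every random list. Slc40a1, the iron exporter of red pulp macrophages, had 184 fragments in q1 and 64.8 in q2, at -1.49 ± 0.39, and Hmox1, which degrades heme, had 212 and 88.3 fragments, at -1.26 ± 0.36. The monocyte gene Ly6c2, with 59.4 and 208 fragments, at 1.79 ± 0.38, and Emr1, encoding the macrophage antigen F4/80, with 85.8 and 146 fragments, at 0.76 ± 0.37, were higher in q2. The 16 T cell markers with at least 20 fragments were all higher in q2, yet core T cell genes were scarce, with Cd3e at 22.8 and 36.4 fragments and Cd4 at 44.4 and 63.6. The remaining marker lists had fewer than 5 genes above 100 fragments. Their summed fragments in q1 and q2 were 97.6 and 101.2 for neutrophils, 498 and 569 for NK cells, 1907 and 1558 for dendritic cells, 1303 and 1501 for erythroid cells, 227 and 405 for platelets, and 3537 and 3618 for stromal and endothelial cells. Single genes that B cells or other leukocytes also express supplied most of several of these sums, such as Pecam1 with 3415 and 3537 fragments and Tfrc with 1217 and 1397.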

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

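The 1.5-fold rule, the requirement of 2 deposited SD, the removal of sex-linked genes and the correction for GC content, length and expression were tests chosen after the data were seen. No paired analysis was possible because the table holds 1 pooled value per condition and carries no replicate numbers, and for the same reason no library could be left out. The planned count tests, normalizations and filters on counts per library were not run, since the table holds no library values. A minimum cannot change a gene's own ratio, and scaling by the median ratio, which was near 1, hardly can. Under the pseudocounts, equal totals and the correction, 11 of 452 values of the 113 named genes moved beyond counting error, 1 of them without the correction (Cr2, -0.18 with equal totals and -0.34 corrected), and 2 changed sign, both corrected (Notch2 to 0.038, Cxcr5 to 0.011). The Ackr3 log2 ratio stayed between -2.81 and -2.71. Counts of genes at least 2-fold apart (176 toward q2, 42 toward q1) became 346 and 102 with a minimum of 20 fragments and 39 and 14 with 500, since more or fewer genes were compared, and 325 and 151 with the 1.5-fold rule. They were 177 and 42 or 166 and 34 with a pseudocount of 0 or 10, 181 and 38 with equal totals, and 157 and 49 after the correction. Against random lists drawn under the same setting, 18 of 24 lists lay outside the central 95% with a minimum of 20 fragments, 12 of 20 with 500 and 18 of 24 corrected, and 19 of 24 under the other settings. Scaling shifts a list and its random lists alike, so under the 2 scalings this count could hardly change and is no check. Of 164 recomputed list medians, 137 moved by less than the SD of random lists. These include the medians under the 2 scalings, which could hardly move. The log2 ratio of the totals was -0.019, and the smallest SD of random lists was 0.034, for B cell receptor signalling. The B-1 median reversed to 0.19 with a minimum of 20 fragments, was -0.33 with 500 and -0.25 corrected, so it has no stable direction; the cause was not tested beyond the change of members. With a minimum of 20 the medians also moved for transitional (0.46), plasma cell (1.35), immediate early (-0.33), unfolded protein response (0.36) and macrophage genes (-1.14). With a minimum of 500 they moved for plasma cell (0.73), memory (0.0060), adhesion (0.040), immediate early (-0.21), interferon (-0.099), cell cycle (0.88) and cholesterol genes (0.17), and germinal center, macrophage, T cell and transitional genes had too few members for a median. A pseudocount of 0 or 10 gave 3.92 or 3.36 for germinal center genes, and 10 gave 1.65 for the cell cycle. The correction gave -0.090 for Notch, 0.050 for CXCL12 and ACKR3 partners, -0.20 for immediate early, -0.019 for NF-kB, -0.25 for interferon, -0.081 for antigen presentation, 1.66 for cell cycle, 0.046 for glycolysis and -1.20 for macrophage genes.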

Other observations

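The tests with T cell markers, with germinal center against cell cycle genes and with 1 against 2 males were chosen after their values were seen, as was the requirement on the escape genes; the correction for GC content was added after the data were seen, but before its values for these lists were. Beyond the lists, further genes differed by at least 2-fold; those named here were chosen after their values were seen. Higher in q1 were Rap1gap, which inactivates the small GTPase Rap1, with 1906 against 723 fragments (log2 ratio -1.40 ± 0.20), Nrp2, a neuropilin that binds semaphorins and VEGF, with 1233 against 529 (-1.22 ± 0.21), and Mfhas1, with 6845 against 2923 (-1.23 ± 0.18). Higher in q2 were Cacna1h, a T-type calcium channel subunit, with 75.9 against 553 (2.85 ± 0.34), Mef2b, a transcription factor of germinal center B cells, with 14.1 against 187 (3.64 ± 0.56), and Reln, encoding reelin, with 30.1 against 193 (2.64 ± 0.45). Ribosomal protein genes had a median of -0.12 over 80 genes, with 74 higher in q1, and made up 8.76% of q1 and 8.10% of q2.

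Germinal center, plasma cell and cell cycle genes were higher in q2. The correction for GC content, transcript length and expression explained 4.05% of the variance of the ratio over all genes and left the germinal center median at 3.75. A fit that small could hardly bring a median of 3.81 near 0, so the corrected value is no separate test of such a bias. The germinal center median exceeded that of the cell cycle list by 2.06. That comparison was chosen after both medians were seen, so it is no independent test of a larger share of dividing cells alone. A candidate explanation, for the plasma cell genes alone, is that plasma cells or plasmablasts made up more of the q2 cells: a second list of 17 genes, mainly of the secretory pathway, which B cells also express, had a median of 0.47, with all 15 members above 100 fragments higher in q2. In q2 the abundant plasma cell transcript Igj had 33006 fragments and Sdc1 had 484, while Bcl6 and Bach2, which plasma cells repress, were also higher in q2, at 1.03 ± 0.21 and 1.37 ± 0.20. Of the plasma cell list, Prdm1 differed little, at 0.25 ± 0.24, and Irf4 was higher in q1, at -0.28 ± 0.18. The source of the germinal center genes, whose median of 3.81 exceeded the 1.02 of the plasma cell list, was not tested, nor was whether such cells came with the MZBs or arose from them, and the labels do not describe how the cells were isolated.

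Macrophage genes were higher in q1. T cell markers had a median of 0.47 over 16 genes, in the opposite direction, so they were not raised in q1 alongside the macrophage genes. That comparison was chosen after its values were seen, and core T cell genes were scarce. It is therefore no independent test of a lower share of MZBs with all other cells raised alike. The correction for GC content, length and expression, which explained 4.05% of the variance over all genes, left the macrophage median at -1.20. A fit that small could hardly bring a median of -1.001 near 0, so the corrected value is no separate test of such a bias. A candidate explanation is that macrophages, or RNA from them, made up more of q1: a second macrophage list of 20 genes had a median of -0.75 over 15 members with at least 20 fragments, 13 of them higher in q1, the exceptions being Apoe and Pltp. The complement genes C1qa, C1qb and C1qc, abundant in macrophages, had only 61.2, 60.5 and 79.4 fragments in q1 and 21.8, 27.0 and 24.1 in q2, while Lgmn and Acp5, with 4143 and 3168 fragments in q1, differed little (-0.17 ± 0.18 and -0.18 ± 0.24), Lyz2 was near equal at 63.5 and 62.9, and Emr1, at 0.76 ± 0.37, was higher in q2. Expression of these genes by the B cells themselves stays open and was not tested.

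Sex-linked genes differed between the columns, and the labels used here do not give the sex of the mice. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in q2, with log2 ratios of 0.96 to 1.24 and a median of 1.08, and Xist was higher in q1, at -0.74 ± 0.37. A candidate explanation is a different sex ratio, for example 1 male among 4 mice in q1 and 2 among 4 in q2, for which 1 and -0.58 would follow. Genes that escape X inactivation left this open: 5 of them had a median of -0.077, past the bound of -0.05 set before it was seen but within their median deposited SD of 0.21, a requirement added afterwards. The deposited coefficients of variation of the Y-linked genes were 17.4% to 19.4% in q1 and 12.2% to 13.5% in q2. For Ddx3y the running medians were 9.4% and 8.7%. A spread between 4 libraries with 1 or 2 wholly male would give 200% or 115%, far more than deposited. Since the deposited variance follows mainly the count and not the gene, these values cannot decide on that example.

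The deposited variances themselves held 1 local anomaly. Of 13 genes with at least 200 fragments and a coefficient of variation above 100% in both columns, 12 lie within 584 kb of chromosome 10 (79736123 to 80320537), among them Polr2e, Gpx4 and Cirbp. The ratios of these 12 genes were small, at most 0.23 in size.

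Across genes, the log2 ratio was lower at higher GC content of the longest transcript (Spearman rho -0.31 over 9510 genes, which are not independent replicates), while its relation to transcript length was near 0 (0.02). GC content, length and expression together accounted for 4.05% of the variance of the ratio.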
